A study of Mus musculus with 26 samples.

How the data were processed

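The data are gene counts of liver RNA from 26 mice. Per the labels' protocols, mice were acclimatised from 4 to 8 weeks with bedding mixed between cages to even out their microbiome, and RNA was extracted with a Qiagen kit. The deposited values are raw counts of reads per gene, with no normalization. Per the submitters' processing notes, bcl2fastq, featureCounts and the mm10 build were used. The aligner, the gene annotation, the strand setting and the tool versions were not given in the sources used here. Because the strand setting is not given, overlapping and antisense genes cannot be told apart with certainty, and genes with near-identical copies are uncertain where reads were split between them. The 26 per-sample files equalled the combined table of 54532 genes in every value. Coordinates are from GENCODE M21 on mm10, in which 54495 of the gene IDs were found.

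The design, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Groups came from the dose in the labels. Within each dose, all pairs of libraries (76 pairs) were compared by chi-square over genes with at least 40 reads, and gave 12.0 to 124 per degree of freedom, so no pair within a dose agreed within sampling noise. Pairs across doses were not compared. Counts were filtered with filterByExpr (14415 genes tested, holding 99.7% of the reads) and scaled by TMM in edgeR 4.0.16 under R 4.3.3. edgeR's quasi-likelihood test with robust spread and Benjamini-Hochberg adjustment was fitted over all 26 mice with terms for dose and for the run of mouse numbers, at an adjusted p of 0.05. The run and dose interaction was fitted on the 5 and 50 mg/kg mice. Normalised values are TMM-scaled CPM. Standard errors were derived from the fold change and the F statistic, and intervals are at 95%.

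Lists of genes were fixed for foreign-chemical receptors, metabolism, stress, inflammation, cell types and the clock (35 lists). Of these, 32 with at least 5 tested genes were tested by camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation and by fry. With an estimated correlation, or by fry for movement in 1 direction, 0 lists passed in any of the 5 comparisons tested. With the preset correlation, nearly every split that moved dose or run labels among the mice also called at least 1 list. A camera call alone thus does not separate a list from chance. The rule named up to 10 genes each way past the threshold at 50 against 0 mg/kg and 5 each way elsewhere, with a mean of at least 1 CPM, up to 4 members of each list described by smallest p, and 11 tested drug metabolism genes in every dose comparison. Zbtb16 was followed in the other comparisons because it was called at 50 against 0 mg/kg.

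The test was tested on simulated counts for 14415 genes with 200 changed. At 50 against 0 mg/kg it recovered 14% of genes changed 1.5-fold, 64% at 2-fold, 94% at 3-fold and 98% at 4-fold. The recovery at 2-fold was 68% at 5 against 0, 60% at 0.5 against 0 and 86% at 50 against 5 mg/kg. The changed genes were drawn only from better expressed genes, and genes were simulated independently with no run difference. Having 200 changed genes also eases the adjusted threshold. These recoveries hold for that setting, so a missing call in the real data does not exclude a change of these sizes. The median SE of a log2 fold change was 0.20 at 50 against 0 mg/kg. Alternatives were DESeq2 1.42.0 (Wald test and its size factors), limma-voom, other filters, thresholds and samples, no run term, each run alone, a surrogate variable from sva 3.50.0, and leaving out each mouse. A planned term for sex was not run because Xist and the Y-linked genes did not split the mice.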

Results

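Liver RNA was sequenced from 26 C57BL/6 mice given benoxacor by oral gavage at 0, 0.5, 5 or 50 mg/kg on 3 consecutive days. Benoxacor is a herbicide safener, a chemical added to herbicide products to protect crop plants from the herbicide. Livers were taken 24 hours after the last dose. There were 5 mice at 0 mg/kg, 5 at 0.5 mg/kg, 8 at 5 mg/kg and 8 at 50 mg/kg, and each library is a separate mouse. The mouse numbers in the labels form 2 runs, 601 to 616 (15 mice) and 619 to 632 (11 mice), and the labels do not say what separates the runs. The run from 601 held 4, 3, 4 and 4 mice at the rising doses, and the run from 619 held 1, 2, 4 and 4. Within each run the numbers rose with dose, with the mice of a dose in 1 block. Dose thus cannot be told apart from anything that follows the number order within a run, and the run term does not remove it. The labels do not say what the order stands for. Total counts ranged from 5433074 to 9088626 per library, with a median of 7105531. The labels give no sex. Xist, expressed from the inactive X chromosome of females, stayed at or below 2.44 CPM, read counts scaled to library size, and the Y-linked Ddx3y ranged from 66.4 to 229 CPM.

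The comparison of 50 with 0 mg/kg asked how the liver transcriptome responds to the highest dose. Zbtb16, which encodes a zinc finger transcriptional repressor, fell by 1.72 on the log2 scale (SE 0.25, 95% confidence interval -2.24 to -1.20), a 3.29-fold lower level. Its mean was 28.5 ± 15.6 CPM (SD, n = 5) at 0 mg/kg, 18.7 ± 7.69 (n = 5) at 0.5, 14.4 ± 8.16 (n = 8) at 5 and 10.6 ± 5.11 (n = 8) at 50. Zbtb16 (ENSMUSG00000066687) lies on chromosome 9 from 48654297 to 48836222 in mm10. It was the single gene of 14415 past an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00333), and 737 genes had an unadjusted p under 0.05 where chance alone gives 721. Within the run from 601 the Zbtb16 means were 22.0, 15.5, 9.47 and 6.78 CPM at the rising doses, and within the run from 619 they were 54.5 (1 mouse), 23.6, 19.4 and 14.5 CPM. All 8 mice at 50 mg/kg lay below the lowest control of their own run, which in the run from 619 was a single mouse. The log2 fold change was -1.71 in the run from 601 (adjusted p = 0.0104) and -1.90 in the run from 619 (adjusted p = 1.0, with 1 control mouse). The call ended without the run term (log2 fold change -1.42, adjusted p = 0.89) and without 0 mg/kg replicate 5, the control of the run from 619 (-1.64, adjusted p = 0.0702).

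**Figure D1:**
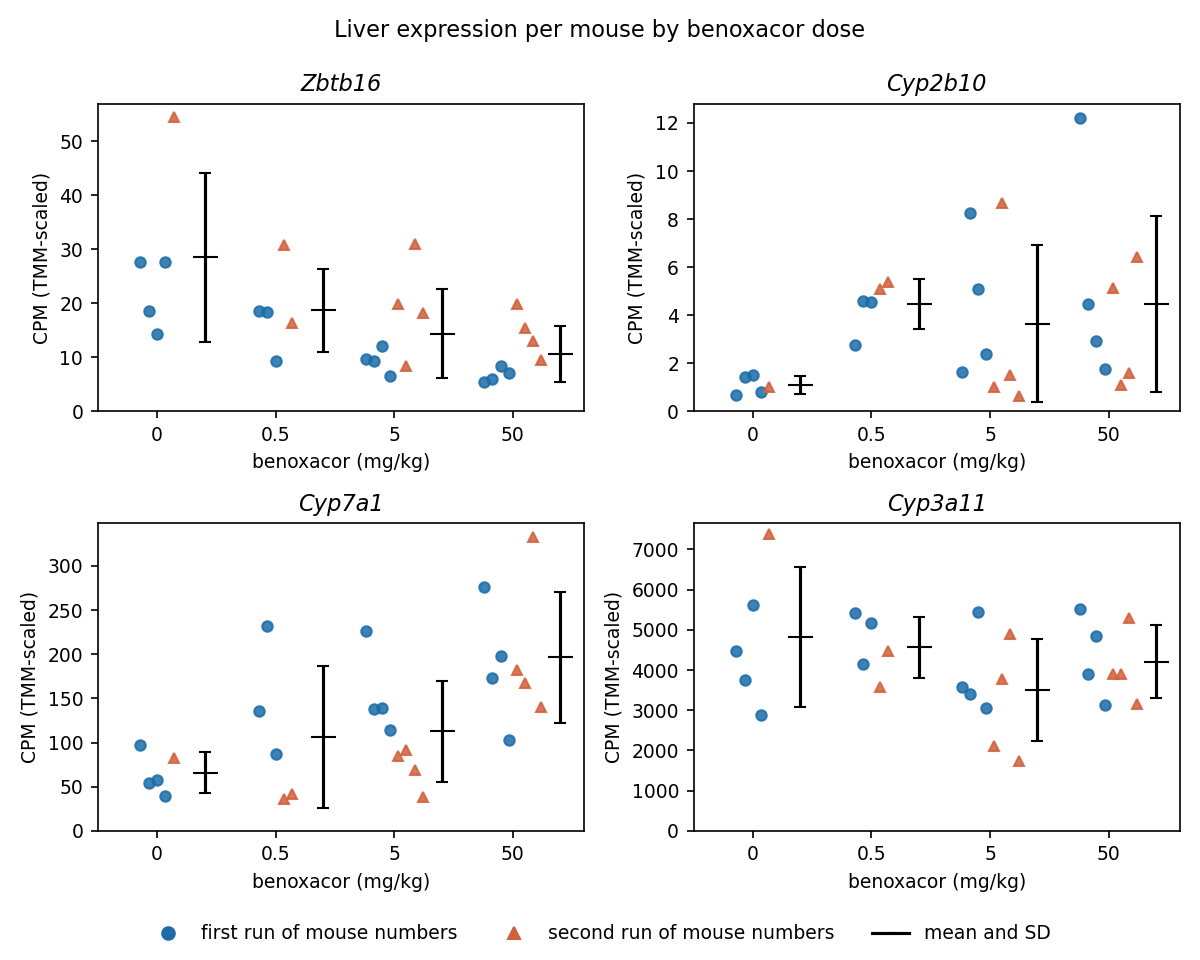
TMM-scaled CPM of Zbtb16, Cyp2b10, Cyp7a1 and Cyp3a11 against benoxacor dose in mg/kg, with 1 point per mouse, circles for the run of mouse numbers from 601, triangles for that from 619, and the mean and SD of each dose beside the points. Zbtb16 averaged 28.5 CPM at 0 mg/kg and 10.6 CPM at 50 mg/kg.

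CAR (Nr1i3) targets, genes under a nuclear receptor that senses foreign chemicals, were higher as a group at 50 than at 0 mg/kg, with positive fold changes in 16 of 20 genes (camera adjusted p = 1.04e-04, and adjusted p = 0.154 with an estimated correlation). Cyp2b10 (ENSMUSG00000030483, chromosome 7 from 25897620 to 25926624), a cytochrome P450 used as a marker of CAR activity, had a log2 fold change of 2.09 ± 0.64 (SE). Its mean was 1.10 ± 0.368 CPM (SD, n = 5) at 0 mg/kg and 4.45 ± 3.66 CPM (n = 8) at 50. It did not pass over all genes in edgeR (adjusted p = 0.721) or adjusted over the list alone (adjusted p = 0.0547). Cyp2c54 (0.70), Cyp2c29 (0.61) and Cyp2c50 (0.48), P450s of a gene cluster whose close copies can share reads, had positive log2 fold changes. PXR (Nr1i2) targets, under a related receptor, were higher as a group with 13 of 19 positive (camera adjusted p = 0.0279, and adjusted p = 0.921 with an estimated correlation), among them the transporter Slco1a4 (1.01), Cyp3a13 (0.55) and the P450 reductase Por (0.49). In the 4 lists past the threshold at this dose, 0 genes passed adjusted over the list alone and 0 over all genes. When dose labels were moved among the mice at 0 and 50 mg/kg, 94 of 100 splits, the real one included, called at least 4 lists. Within the runs from 601 and 619 the values were 2.25 and 1.80 for Cyp2b10 and 0.72 and 0.44 for Cyp2c29, while Cyp2c54 (1.01 and -0.11) and Cyp2c50 (0.70 and -0.13) turned direction in the run from 619. Without 0 mg/kg replicate 5 they had 1.06 and 0.73, and Cyp2c54 passed over all genes in the run from 601 (adjusted p = 0.0401).

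Acute phase genes, which encode proteins the liver secretes in inflammation, were also higher as a group at 50 mg/kg, with 25 of 29 positive (camera adjusted p = 0.00229, and adjusted p = 0.921 with an estimated correlation). The protease inhibitor Serpina3m had a log2 fold change of 0.93, and the orosomucoids Orm1 and Orm3, near-identical copies whose reads can be split, had 0.56 and 1.73. Orm3 had 2.60 without 0 mg/kg replicate 2 and 1.11 without 50 mg/kg replicate 5. Genes of the list ER stress and integrated stress response, which answer unfolded protein and amino acid shortage, were lower as a group, with 17 of 26 negative (camera adjusted p = 0.0279, and adjusted p = 0.921 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, had -0.81, the transcription factor Atf5 had -0.65 and Herpud1, a factor of protein degradation at the endoplasmic reticulum, had -0.51, while the transcription factor Atf4 had 0.25. All 4 turned direction in the run from 619, with its 1 control mouse, where Mthfd2 had 0.68, Atf5 0.010, Herpud1 0.14 and Atf4 -0.018. Atf5 had -0.36 without 0 mg/kg replicate 4. The PXR (Nr1i2) targets and ER stress and integrated stress response lists lost their calls without the run term (adjusted p = 0.0649 for both) and with an index of 14 clock genes in the fit (0.183 and 0.284), and the Acute phase and stress lists lost theirs within the run from 601 (0.060 for both), while CAR (Nr1i3) targets had adjusted p = 4.4e-07 there. The PXR list also lost its call without 0 mg/kg replicates 1 (0.236), 4 (0.116) or 5 (0.0512) or 50 mg/kg replicates 1 (0.131), 3 (0.0506) or 5 (0.0566), and the stress list without 0 mg/kg replicates 1 (0.236) or 3 (0.0928) or 50 mg/kg replicates 1 (0.244), 2 (0.120), 5 (0.0566), 6 (0.0523) or 7 (0.125).

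Cyp7a1 (ENSMUSG00000028240, chromosome 4 from 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, averaged 66.0 ± 23.4 CPM (SD, n = 5) at 0 mg/kg and 197 ± 74.4 CPM (n = 8) at 50. Its log2 fold change of 1.75 ± 0.40 (SE) did not pass in edgeR (adjusted p = 0.614), and DESeq2 called it (adjusted p = 0.00795), as did the fit with 1 surrogate variable (1.90, adjusted p = 0.0403). The other 9 genes named in advance did not pass either. Their log2 fold changes were 0.23 ± 0.30 for Cyp2c55, -0.18 ± 0.25 for Cyp3a11, 0.39 ± 0.46 for Cyp1a1, 0.13 ± 0.22 for Cyp1a2, 0.28 ± 0.46 for Cyp4a10 and -0.06 ± 0.84 for Cyp4a14. For Nqo1, Gstm3 and Ces2a they were 0.46 ± 0.34, 0.10 ± 0.34 and 0.07 ± 0.21. Leaving out 1 mouse moved Cyp2c55 as far as 0.028 (50 mg/kg replicate 3) and 0.48 (0 mg/kg replicate 4), Cyp1a1 to 0.098 and 0.67 (0 mg/kg replicates 5 and 4), Cyp4a10 to 0.11 (50 mg/kg replicate 1) and 0.86 (0 mg/kg replicate 3), and Nqo1 to 0.77 (0 mg/kg replicate 3). Cyp2c55 turned direction in the run from 619 (-0.011), Cyp3a11 and Cyp4a14 in the run from 601 (0.055 and 0.31), and Cyp3a11 (0.11), Cyp1a2 (-0.0058) and Ces2a (-0.089) without 0 mg/kg replicate 5. Ces2a also turned with 1 surrogate variable (-0.014), and Cyp4a14, close to 0, under several further alternatives, up to 1.07 without 0 mg/kg replicate 3. Gstm3 turned without 0 mg/kg replicates 1 (-0.070), 2 (-0.023) or 5 (-0.040) or 50 mg/kg replicate 8 (-0.055). Targets of the dioxin receptor AhR (median log2 fold change 0.10, adjusted p = 0.249), of the fatty acid receptor PPAR-alpha (0.03, 0.519) and of the oxidative stress factor NRF2 (-0.05, 0.796) did not pass as groups. Neither did cholesterol synthesis (0.11, 0.214), proliferation (0.01, 0.921) or p53 and DNA damage genes (-0.17, 0.0953).

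**Figure D2:**
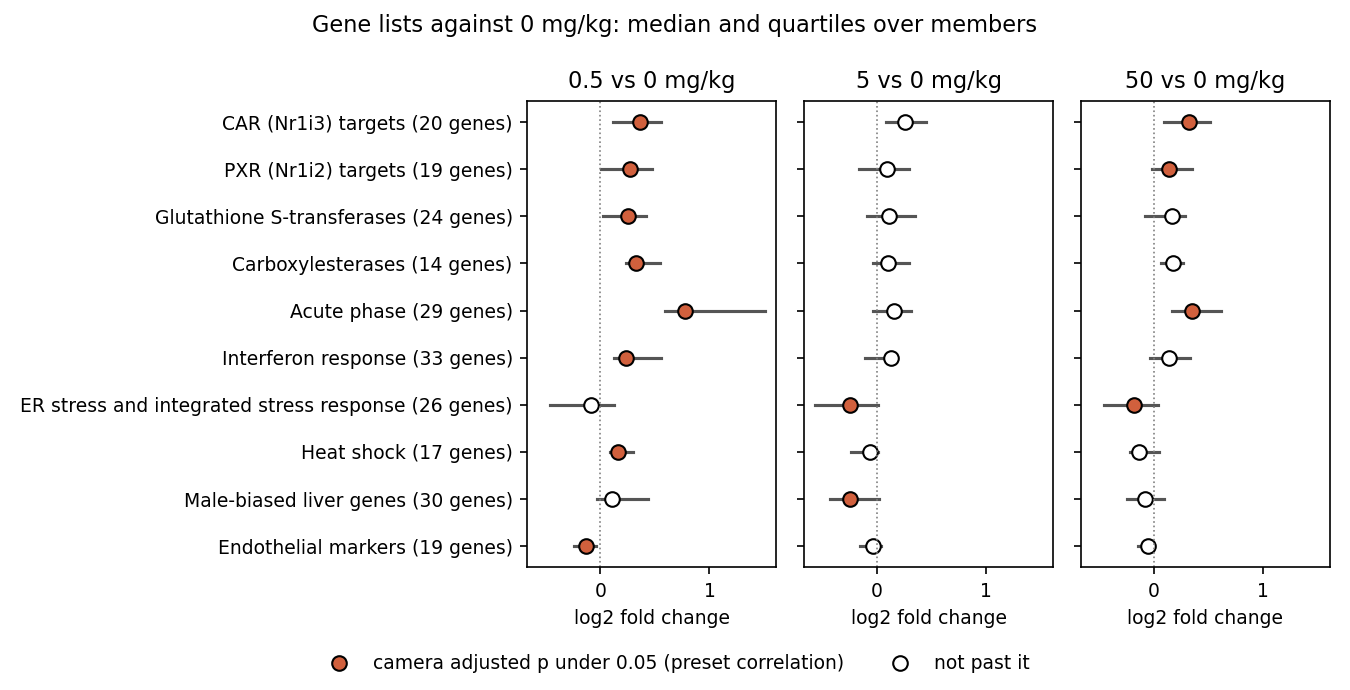
Log2 fold changes against 0 mg/kg of the 10 gene lists past the threshold at any dose, as the median (point) and quartiles (line) over the genes of each list, with filled points for lists past a camera adjusted p of 0.05. The median of the 20 CAR targets was 0.32 at 50 against 0 mg/kg.

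At 5 against 0 mg/kg, genes of the list ER stress and integrated stress response were lower as a group, with 19 of 26 negative (camera adjusted p = 0.00968, and adjusted p = 0.879 with an estimated correlation). Adjusted over the list alone, 2 of them fell and 0 over all genes. Dnajb9, a chaperone partner of the endoplasmic reticulum, fell by 0.92 on the log2 scale (adjusted p over the list alone 0.0124), and Herpud1 fell by 0.66 (0.0329). Sesn2, a stress-induced regulator of growth signalling, had -0.75 and Mthfd2 had -0.98, which turned to 0.48 in the run from 619, where Herpud1 had -0.086 and Sesn2 had -0.019. Sesn2 had -0.50 without 0 mg/kg replicate 2. The list lost its call without 0 mg/kg replicate 1 (adjusted p = 0.0611) or 5 mg/kg replicate 1 (0.0995). Male-biased liver genes, which are more abundant in male than female livers, were lower as a group, with 22 of 30 negative (camera adjusted p = 0.00968, and adjusted p = 0.879 with an estimated correlation), among them Cspg5 (-1.0, and 0.13 in the run from 619) and the major urinary protein gene Mup20 (-0.80), whose near-identical copies make it uncertain. In 5 mg/kg replicate 6, Mup transcripts took 0.653% of the counts, the lowest of the 26 libraries, and without that mouse the Male-biased liver genes had adjusted p = 0.164, without 5 mg/kg replicates 6 and 8 they had 0.176, and without 0 mg/kg replicate 4 they had 0.0638. In this list 0 genes passed adjusted over the list alone and 0 over all genes.

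CAR (Nr1i3) targets (16 of 20 positive, camera adjusted p = 0.0648), PXR (Nr1i2) targets (12 of 19, 0.231) and Acute phase genes (20 of 29, 0.168) did not pass as groups at 5 against 0 mg/kg, each with adjusted p = 0.879 with an estimated correlation. No gene passed at 5 against 0 mg/kg in edgeR's quasi-likelihood test (smallest adjusted p = 0.203), with 891 genes at an unadjusted p under 0.05. Limma-voom called 0 genes and DESeq2 called 4, all lower, which were Zbtb16, Zbtb40, Stx5a and Gpr137b-ps, named after their values were seen. Zbtb16 had a log2 fold change of -1.28 ± 0.25 (SE) in edgeR (adjusted p = 0.203), and all 8 mice at 5 mg/kg lay below the lowest control of their run. In the run from 619 that control was a single mouse at 54.5 CPM, above the mice of every other dose, so its comparison does not tell the doses apart. The 11 genes named in advance ranged from -0.45 for Cyp3a11 (-0.15 without 0 mg/kg replicate 5) to 1.79 for Cyp2b10, with 0.82 for Cyp7a1 (-0.21 in the run from 619), and 0 of them passed (smallest adjusted p = 0.780). Without 0 mg/kg replicate 4 edgeR called 3 genes, all lower, among them Dnajb9 (-1.12, adjusted p = 0.0288), and without 5 mg/kg replicate 7 it called 1, Zbtb16 (-1.40, adjusted p = 0.0468).

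At 0.5 against 0 mg/kg, all 29 genes of the Acute phase list had positive fold changes (camera adjusted p = 2.26e-15, and adjusted p = 0.433 with an estimated correlation). Of these, 14 rose when adjusted over the list alone and 0 over all genes. The log2 fold changes were 2.19 for the serum amyloid gene Saa3, 1.18 for Orm1, 1.16 for Serpina3m and 0.74 for C-reactive protein (Crp), which had -0.14 in the run from 619. In the run from 601, Serpina3m (1.5, adjusted p = 0.0453) and Crp (1.08, 0.0418) passed over all genes. The serum amyloid gene Saa1 was at 2311 and 3233 CPM in 0.5 mg/kg replicates 1 and 2, and at most 655 CPM in the other 24 mice. Both belong to the run from 601, where they were 2 of its 3 mice at 0.5 mg/kg. The values of that run at this dose thus come mostly from them. Without replicate 2 alone the log2 fold changes were 1.37 for Saa3, 0.75 for Orm1, 0.71 for Serpina3m and 0.38 for Crp, and without both mice they were 0.22, 0.40, 0.73 and 0.22. Without these 2 mice the acute phase list had adjusted p = 0.142. Interferon response genes were higher as a group, with 28 of 33 positive (camera adjusted p = 5.00e-04, and adjusted p = 0.604 with an estimated correlation), including the GTPase Irgm1 (0.56) and the antiviral gene Ifit3 (0.83). The Interferon response list had adjusted p = 0.966 without the same 2 mice and 0.0587 without 0.5 mg/kg replicate 1 alone. Heat shock genes, with 14 of 17 positive (adjusted p = 0.0319) and Hspb8 at 0.48, had adjusted p = 0.604 with an estimated correlation and 0.142 without the 2 mice. The Heat shock call also ended without 0 mg/kg replicates 4 (0.0901) or 5 (0.320) or 0.5 mg/kg replicates 1 (0.0587), 4 (0.0965) or 5 (0.0681). In the interferon and heat shock lists 0 genes passed adjusted over the list alone and 0 over all genes.

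CAR (Nr1i3) targets were higher at 0.5 mg/kg, with 16 of 20 positive (camera adjusted p = 9.30e-05, and adjusted p = 0.187 with an estimated correlation), and had adjusted p = 2.4e-04 without the 2 mice of high Saa1. Adjusted over the list alone, 3 genes rose and 0 over all genes. These were Cyp2b10 (log2 fold change 2.11), Cyp2c50 (0.67) and Cyp2c29 (0.72), each at adjusted p = 0.0420 over the list, and Cyp2c50 had -0.043 in the run from 619 and 0.93 in the run from 601, where it passed over all genes (adjusted p = 0.0418). In the run from 601 the mice of high Saa1 were 2 of the 3 at 0.5 mg/kg. The lowest Cyp2b10 value at 0.5 mg/kg was 2.75 CPM and the highest control value was 1.51 CPM. The higher doses overlapped the controls, with lowest values of 0.622 CPM at 5 mg/kg and 1.12 CPM at 50 mg/kg. PXR targets were higher, with 14 of 19 positive (camera adjusted p = 8.87e-04, and adjusted p = 0.604 with an estimated correlation), and Cyp3a13 rose by 0.91 (adjusted p over the list alone 0.0329), the 1 gene of the list to do so, with 0 over all genes. Glutathione S-transferases, which conjugate reactive chemicals, were positive in 18 of 24 (camera adjusted p = 0.00387), with Gsta3 at 0.58, while Gstp3 had -0.48. Carboxylesterases were positive in 11 of 14 (adjusted p = 0.00662), with Ces1g at 0.56. Endothelial markers were negative in 16 of 19 (adjusted p = 0.00662), with the surface receptor Eng at -0.32 and von Willebrand factor (Vwf) at -0.58. These 3 lists each had adjusted p = 0.604 with an estimated correlation, and 0 of their genes passed adjusted over the list alone and 0 over all genes. The calls ended without 0.5 mg/kg replicates 4 or 5 for Glutathione S-transferases (0.0874 and 0.0694) and Carboxylesterases (0.160 and 0.0681), and without 0 mg/kg replicate 2 or 0.5 mg/kg replicate 5 for Endothelial markers (0.0595 and 0.123). Members of the Gst and Ces1 families share reads with close copies, so their single values are uncertain.

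No gene passed at 0.5 against 0 mg/kg in edgeR's quasi-likelihood test (smallest adjusted p = 0.391), with 1008 genes at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 called 7. Within the run from 601, where the mice of high Saa1 were 2 of the 3 at 0.5 mg/kg, edgeR called 33. Zbtb16 had -0.74 ± 0.27 (SE), with 1 of 3 mice and 2 of 2 mice below the lowest control of their runs. In the run from 619 that control was a single mouse, above the mice of every other dose. Of the 11 genes named in advance 0 passed (smallest adjusted p = 0.492), with 2.11 for Cyp2b10 and 0.63 for Cyp7a1. Cyp7a1 turned direction in the run from 619 (-1.05) and without the 2 mice of high Saa1 (-0.16), and had 0.19 without 0.5 mg/kg replicate 2 alone. The 3 comparisons with 0 mg/kg share the same 5 control mice, so their values are not independent.

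At 50 against 5 mg/kg, genes of the list Stellate cell and fibroblast markers were lower as a group, with 16 of 19 negative (camera adjusted p = 0.00322, and adjusted p = 0.936 with an estimated correlation), among them Sod3 (-0.54), the collagen gene Col1a2 (-0.88) and smooth muscle actin (Acta2, -1.44). Hgf of this list went the other way at 0.56. The library of 5 mg/kg replicate 8 held 59.2 CPM of Col1a2, against at most 20.8 CPM in the other 25 libraries, together with transcripts of steroid-producing cells. Without 5 mg/kg replicates 6 and 8 the list had adjusted p = 0.538, and without replicate 8 alone it had 0.0880. Without replicate 8 alone the log2 fold changes were -0.26 for Col1a2, -0.62 for Acta2 and -0.19 for Scd2, and that of Acta2 turned direction without the 2 mice (0.063). Glucuronosyl- and sulfotransferases, which conjugate drugs and hormones, were higher, with 20 of 23 positive (camera adjusted p = 0.00435, and adjusted p = 0.936 with an estimated correlation), including Ugt1a7c (1.33) and Ugt1a6a (0.51), which share exons. Sult1c2 of this list went the other way at -0.68. The list Glucuronosyl- and sulfotransferases had adjusted p = 0.326 without the same 2 mice and 0.0880 without replicate 8 alone. Male-biased liver genes were higher, with 20 of 30 positive (camera adjusted p = 0.00744, and adjusted p = 0.936 with an estimated correlation), including Mup20 (0.48) and Slco1a1 (0.42). Moxd1, the member with the smallest p, went the other way at -2.85 ± 1.46 (SE). It was at 98.9 CPM in 5 mg/kg replicate 8, against at most 19.3 CPM in the other 25 libraries. The direction of the list turned without the 2 mice (adjusted p = 0.982) or without 5 mg/kg replicate 6 alone (0.965). The call also ended without 50 mg/kg replicates 3 (0.0808) or 4 (0.0620), and the log2 fold change of Mup20 was -0.32 in the run from 601. It was 0.28 and 0.29 without 5 mg/kg replicate 6 or 50 mg/kg replicate 7, where Slco1a1 had 0.27 and 0.24. Fatty acid synthesis (SREBP1) genes were lower, with 18 of 25 negative (camera adjusted p = 0.00972, and adjusted p = 0.936 with an estimated correlation), including Pnpla3 (-1.69) and Scd2 (-1.61), while Elovl6 had 0.40. The log2 fold change of Scd2 turned direction without the 2 mice (0.18) and in the run from 601 (0.21). The call of the fatty acid list ended without 50 mg/kg replicates 3 (0.0831) or 4 (0.211). In the 4 lists 0 genes passed adjusted over the list alone and 0 over all genes.

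No gene passed at 50 against 5 mg/kg in edgeR's quasi-likelihood test (smallest adjusted p = 0.962), with 699 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0. Zbtb16 had -0.44 ± 0.23 (SE), and -0.29 without 5 mg/kg replicate 7. Of the 11 genes named in advance, Cyp7a1 had 0.93 and Cyp2b10 had 0.30, with -0.093 without 50 mg/kg replicate 1 and 0.77 without 5 mg/kg replicate 6. The dose difference was also compared between the runs. No gene of 13418 passed for this interaction in edgeR (smallest adjusted p = 0.982), with 656 at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0.

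Between the runs of mouse numbers, 10 genes rose and 3 fell in the run from 619. Npas2 (ENSMUSG00000026077, chromosome 1 from 39193731 to 39363236), an activator of the circadian clock, rose by 3.46 ± 0.58 (SE) on the log2 scale (edgeR adjusted p = 0.00987), from 0.289 ± 0.401 CPM (SD, n = 15) to 2.93 ± 2.0 CPM (n = 11). Its partner Arntl rose by 1.30 ± 0.26 (adjusted p = 0.0490), Zbtb16 by 1.01 ± 0.18 (0.0186), and the choline kinase gene Chka by 1.29 (0.0186). Gm16066 rose by 1.45 (0.0186) and overlaps Chka on chromosome 19, where Gm16066 ends at 3852419 and Chka starts at 3851773, so reads of the overlap cannot be assigned with certainty. The rhythmic nuclease gene Noct fell by 1.23 ± 0.22 (adjusted p = 0.0220), Crybg2 fell by 1.25 (0.0439) and the polarity gene Lin7a fell by 0.62 (0.0488). Of the 22 clock genes, 4 were higher and 10 lower adjusted over the list alone, against 2 higher and 1 lower over all genes (camera adjusted p = 1.94e-04, and adjusted p = 0.447 with an estimated correlation). In fry's test for changes in either direction, the Circadian clock list passed between the runs (adjusted p = 4.15e-04), as did the lists Glucocorticoid targets and metallothioneins (0.00332) and Fatty acid synthesis (SREBP1) (0.0151), and 0 lists passed it between doses. The clock repressor Per1 had -1.01 (adjusted p over the list alone 9.27e-04). Leaving out each of the 26 mice ended the call of Lin7a in 20 fits and of Arntl in 19 (adjusted p up to 0.113 for both), of Crybg2 in 15 (up to 0.104) and of Noct in 9 (up to 0.0610). It ended that of Gm16066 in 3 (without 5 mg/kg replicates 3 or 4 or 50 mg/kg replicate 6, up to 0.0521), of Zbtb16 in 2 (without 5 mg/kg replicate 4 or 0.5 mg/kg replicate 4, up to 0.0548), of Chka in 1 (without 5 mg/kg replicate 4, 0.0508) and of Npas2 in 0. With limma-voom the calls of Npas2 (adjusted p = 0.0504), Zbtb16, Noct and Crybg2 (0.0526 each), Lin7a (0.0527) and Arntl (0.0572) ended, and without 5 mg/kg replicates 6 and 8 those of Noct (0.0696), Crybg2 (0.0759), Arntl (0.0896) and Lin7a (0.108). The calls of Noct (0.0539) and Arntl (0.106) ended with no filter on low counts, and those of Arntl and Lin7a (0.0532 each) with a stricter one. With an index of 14 clock genes in the fit, the adjusted p of these 8 genes ranged from 0.336 for Lin7a to 0.717 for Arntl. Arntl and Npas2 are members of the index and were adjusted in part for themselves, so their lost calls carry no information.

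**Figure D3:**
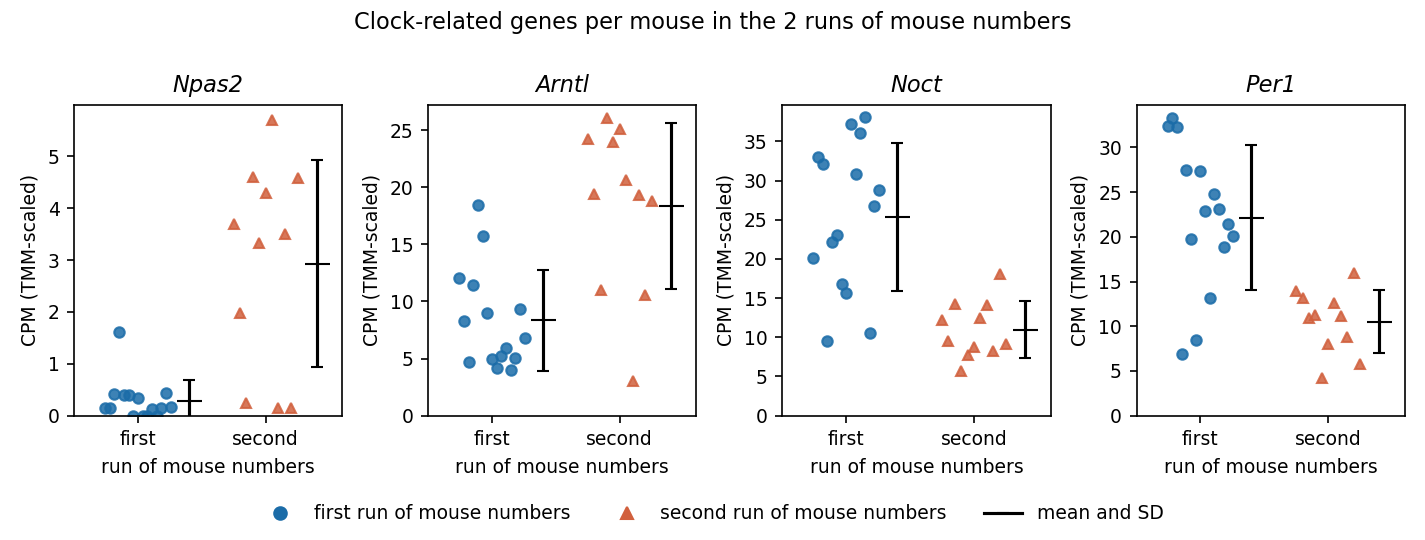
TMM-scaled CPM of the clock-related genes Npas2, Arntl, Noct and Per1 in the 2 runs of mouse numbers, with 1 point per mouse and the mean and SD of each run beside the points. Npas2 averaged 0.289 CPM in the run from 601 and 2.93 CPM in the run from 619.

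Mitochondrially encoded transcripts were lower in the run from 619 in 13 of 13 genes (camera adjusted p = 1.70e-05, and adjusted p = 0.835 with an estimated correlation), with mt-Co2 at -0.69. Red blood cell markers were higher in 7 of 7 (adjusted p = 0.0192), with the globin gene Hbb-bs, which has close copies, at 0.52. Glucuronosyl- and sulfotransferases were lower in 17 of 23 (adjusted p = 0.0241), with Sult1d1 at -0.50, while Ugt3a1 had 0.24. The last 2 lists each had adjusted p = 0.835 with an estimated correlation, and 0 genes of these 3 lists passed adjusted over the list alone or over all genes. The Red blood cell markers call ended without 5 mg/kg replicates 1 (0.0524) or 8 (0.0714), 50 mg/kg replicate 2 (0.0511) or 0.5 mg/kg replicate 4 (0.0505), and that of Glucuronosyl- and sulfotransferases without 5 mg/kg replicates 3 (0.0595) or 8 (0.186). Without 5 mg/kg replicates 6 and 8 they had adjusted p = 0.0657 and 0.193. The count of 13 genes moved to 2 without 5 mg/kg replicate 4 and to 60 without 0 mg/kg replicate 4 or without 50 mg/kg replicate 7, and DESeq2 called 108 and limma-voom 6.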

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

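The tests of the sex of the mice for the runs and of a response to dose for the steroid genes, and the weighing of the run from 601 against a dependence of Zbtb16 on 1 mouse, were chosen only after the result was seen. Within each dose, 57 genes and 4 library measures were searched for a single mouse far from the rest of its group. Of 244 groups, 15 held such a mouse. Chance flags about 1 in 20 groups.

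At 0.5 mg/kg, replicate 1 had 2.75 CPM of Cyp2b10 (others 4.57 to 5.39) and a total count of 5433074 (others 8106695 to 9088626). Replicate 2 had 464 CPM of Cyp3a13 (others 242 to 273), and replicate 3 had 119 CPM of Hspb8 (others 156 to 164). At 0 mg/kg, replicate 4 had 37.7 CPM of Dnajb9 (others 94.5 to 122) and replicate 5 had 8.28 CPM of Sod3 (others 14.8 to 17.7). At 5 mg/kg, replicate 6 had 701 CPM of Mup20 (others 2738 to 8292) and 25 CPM of Ifit3 (others 9.07 to 12), and replicate 8 had 59.2 CPM of Col1a2 (others 7.04 to 15.9) and 131 CPM of Scd2 (others 3.97 to 14.8). At 50 mg/kg, replicate 7 had 170 CPM of Cyp1a2 (others 304 to 460) and 277 CPM of Hbb-bs (others 62.6 to 125). Replicate 6 had 971 CPM of Gsta3 (others 1593 to 2034), replicate 4 had 62.4 CPM of Eng (others 45.3 to 52.7) and replicate 1 had 2.56 CPM of Ugt1a7c (others 0.890 to 1.46).

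Zbtb16 was lower at 50 than at 0 mg/kg. A difference in clock phase, as far as an index of 14 clock genes measures it, is argued against as the whole cause. With the index in the fit the log2 fold change of Zbtb16 was -1.64 ± 0.26 (SE, adjusted p = 0.0200), and an index of 9 other corticosteroid targets left it at -1.75 ± 0.26 (adjusted p = 0.00474). The call ended without 1 of the 13 mice, 0 mg/kg replicate 5 (-1.64, adjusted p = 0.0702), so by the rule set beforehand the call over all mice depended on that mouse. The size of the fall changed little without it, and the run from 601, which does not hold that mouse, gave -1.71 (adjusted p = 0.0104). Chance could not be excluded for the count of genes, since 9 of 100 splits of these mice called at least the real 1 gene, with a highest other count of 4. An effect of dose stays open as a hypothesis.

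The runs of mouse numbers differed in clock genes. With the clock index in the fit the median ratio of the fold changes of the 11 called genes outside the index was 0.743 (interquartile range 0.623 to 0.831). This stayed above the level set beforehand for clock phase as the cause, and phase may account for part of the difference. Whether it accounts for the whole cannot be decided, since the index measures phase with error. The count went from 13 to 0, and the called genes inside the index were adjusted in part for themselves. Over the 11 outside it, the median absolute log2 fold change went from 1.01 to 0.71 and the median SE from 0.18 to 0.22. Library size left the ratio at 1.03 over 13 genes, and sex was argued against by a highest Xist of 2.44 CPM. Of 100 splits, 3 gave at least 13 genes, with the real one included and other counts of 80 and 2420. A count of 13 was thus uncommon among the splits, but chance is not excluded. The splits also moved run labels across doses, and the cause of the largest count was not tested. What separates the runs stays open since the labels do not say what they are.

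The library of 5 mg/kg replicate 8 held 911 CPM of the steroid transport gene Star, against at most 6.11 CPM elsewhere. A candidate source is adrenal tissue in the sample, since 7 of 8 further adrenal cortex markers were at least 10 times the highest other library, with Hsd3b1 at 12591 reads (highest other 1), Cyp11a1 at 4557 (0) and Cyp11b1 at 4482 (2). The exception was Mrap at 1.47 times. The adrenal medulla genes Chga and Th had 2716 and 1315 reads, and 4 kidney markers had 0. A response to dose was argued against, since 1 of the other 7 mice at 5 mg/kg had Star above every control.

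Other splits of the mice were drawn for the remaining counts, 100 each with the real one. At 0.5 against 0 mg/kg the groups are of equal size, and some splits drawn there were mirrors of each other that give the same test. Some divisions of the mice are thus counted more than once at that dose. Where the real count of genes was 0, each of the 100 splits is as large, so the splits decide nothing at 5 against 0, 0.5 against 0 or 50 against 5 mg/kg or for the interaction. The highest other counts there were 3, 269, 1809 and 4 in that order. Those of 269 and 1809 genes came from 1 split each, and their cause was not tested, since the mice in these splits were not compared. Chance could not be excluded for the numbers of lists at 50 against 0 mg/kg (real 4, highest other 17, 94 as large), 5 against 0 (2, 17, 98), 0.5 against 0 (8, 17, 52), 50 against 5 (4, 17, 96) and the runs (4, 18, 95). At least 1 list was called in 99, 99, 95, 99 and 99 of the splits other than the real one, in that order. Except at 0.5 against 0 mg/kg, nearly all splits called at least as many lists as the real labels. The camera p of the CAR list at 50 against 0 mg/kg was 3.24e-06, the smallest other was 1.19e-06 and 2 of 100 splits were as small. A p this small was uncommon among the splits for this list taken alone. Chance is not excluded, since it was 1 of 32 lists and the splits moved dose labels across the runs.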

How the results depend on the processing

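The fits with the clock index, without 5 mg/kg replicates 6 and 8, without the 2 mice of high Saa1 and without the robust option, and the list alternatives outside 50 against 0 mg/kg, were chosen only after the result was seen. Of 2079 alternative values of 76 gene results, 1933 kept their direction and side of the threshold, 94 lost and 13 gained a call, and 39 reversed. Most of these results were not called to begin with, and an uncalled result that stayed uncalled counts as kept. The 94 lost calls all come from Zbtb16 at 50 against 0 mg/kg and the called genes named between runs. The count of 1933 thus does not measure how stable the calls were. Where not stated, the cause was not tested. The count at 50 against 0 mg/kg was 1 and became 3 with DESeq2 (Cyp7a1, Zbtb16 and Hspa1b), 0 without the run term, 2 with a surrogate variable (Cyp7a1 and Zbtb16), 4 in the run from 601 (Zbtb16, Hspa1b, Sult1a1 and Cyp2c54), 0 in the run from 619 with its 1 control, assumed to vary like the other groups, and 2 with the clock index (Zbtb16 and Hspa1b); genes outside the rule were named after their values were seen. The 0 at 5 against 0 became 4 with DESeq2, and the 0 at 0.5 against 0 became 7 with DESeq2 and 33 in the run from 601. In that run the mice of high Saa1 were 2 of the 3 at 0.5 mg/kg. The 13 between runs became 62 at an adjusted p of 0.1, 8 at 2-fold, 108 with DESeq2, 6 with limma-voom, 7 with the stricter filter, 38 with a surrogate variable and 0 with the clock index. The lists became 0 in each comparison with an estimated correlation and 0 with fry for movement in 1 direction, and the 4 at 50 against 0 became 2 without the run term and 2 in the run from 601. Leaving out each mouse gave 0 to 1 genes at 50 against 0 mg/kg (0 without 0 mg/kg replicate 5), 0 to 3 at 5 against 0 (3 without 0 mg/kg replicate 4), 0 to 0 at 0.5 against 0 and 50 against 5, 2 to 60 between runs and 0 to 2 for the interaction (2 without 50 mg/kg replicate 1), and 2 to 8, 2 to 9, 5 to 11, 2 to 7 and 3 to 7 lists in the order 50, 5 and 0.5 against 0, 50 against 5 and runs. Log2 fold changes reversed in the run from 619 at 50 against 0 for Cyp2c55 (-0.011), Cyp2c54 (-0.11), Cyp2c50 (-0.13), Atf4 (-0.018), Atf5 (0.010), Herpud1 (0.14) and Mthfd2 (0.68), at 5 against 0 for Cyp7a1 (-0.21), Mthfd2 (0.48) and Cspg5 (0.13), and at 0.5 against 0 for Cyp7a1 (-1.05), Crp (-0.14) and Cyp2c50 (-0.043). In the run from 601 they reversed for Cyp3a11 (0.055) and Cyp4a14 (0.31) at 50 against 0 and for Scd2 (0.21) and Mup20 (-0.32) at 50 against 5. Cyp4a14 also reversed with limma-voom (0.45), with the compared doses alone (0.068), without the run term (0.082) and without 5 mg/kg replicates 6 and 8 (0.025), and Ces2a with a surrogate variable (-0.014). Without those replicates Scd2 (0.18), Acta2 (0.063) and the male-biased list (adjusted p = 0.982) reversed at 50 against 5, and Cyp7a1 (-0.16) at 0.5 against 0 without the 2 mice of high Saa1. Leaving out each mouse reversed Cyp3a11 (-0.32 to 0.11), Cyp1a2 (-0.0058 to 0.25), Cyp4a14 (-0.49 to 1.07), Gstm3 (-0.070 to 0.34) and Ces2a (-0.089 to 0.19) at 50 against 0, and Cyp2b10 (-0.093 to 0.77) and the male-biased list (adjusted p = 1.70e-04 to 0.965, the latter without 5 mg/kg replicate 6) at 50 against 5. A planned fit with a term for sex was not run because Xist and Ddx3y did not split the mice, and lists were not tested in the run from 619 alone. No paired analysis was possible because replicate numbers follow accession order and do not pair mice. Depth limits genes near 1 CPM such as Cyp2b10 and Npas2.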

Other observations

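The library of 5 mg/kg replicate 6 stood outside the range of the other 25 libraries in several genes. Cyp4a12a was at 35.1 CPM (142 to 587 in the others), Cyp7b1 at 38.1 CPM (122 to 501), Serpina12 at 1.86 CPM (22.6 to 106) and Mup7 at 290 CPM (6870 to 40368). Abcd2 was at 73.3 CPM (6.23 to 25.7), Atp6v0d2 at 10.6 CPM (0.137 to 2.43) and Cyp17a1, a steroid enzyme, at 26.3 CPM (0.619 to 4.72). Xist was at most 2.44 CPM in all 26 libraries. Cyp4a12a, Cyp7b1, Serpina12 and Mup7 are on the fixed list of male-biased liver genes, and Abcd2, Atp6v0d2 and Cyp17a1 on that of female-biased liver genes. These genes were chosen after their values were seen, and no fixed list was tested in this library alone.

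In 0.5 mg/kg replicates 1 and 2, further transcripts of the inflammatory response were high beside Saa1. Lcn2, an iron-binding defence protein, was at 32.8 and 57.8 CPM, against at most 11.2 CPM in the other 24 mice. Saa3 was at 48.5 and 91.9 CPM, against at most 12.1 CPM, and the neutrophil gene S100a9 was at 18.6 and 7.28 CPM, against at most 7.24 CPM. These values were chosen after they were seen.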
